A study of Mus musculus with 8 samples.

How the data were processed

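The data are RNA sequencing profiles of mouse embryonic stem cells grown on embryonic fibroblast feeder cells. There were 8 libraries in 4 groups, with 2 libraries per group that the labels call biological duplicates. The untreated group carried a floxed Mll1 gene and a tamoxifen-activated Cre recombinase. A second group received MM401, an inhibitor of the histone methyltransferase MLL1, at 100 µM. Another group received 4-hydroxytamoxifen at 5 µM, which deletes the floxed Mll1 gene. The 2i group received the MEK inhibitor PD at 1 µM and the GSK3 inhibitor CHIR99021 at 3 µM. Each treatment lasted 5 days. Per the labels' protocols, the MM401 and deletion cultures were in serum medium and the 2i cultures were in medium with serum replacement, so the 2 inhibitors of 2i and any difference in medium cannot be told apart. The medium of the untreated group is not given in the sources used here, so a difference in medium may enter any comparison with it. No vehicle-treated group was among the 8 libraries.

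The submitters' processing notes name TopHat2 2.1.1, SAMtools 1.5, deepTools and the mm10 build, without their roles. Per the file headers, the deposited FPKM values (fragments per kilobase of transcript, scaled to the number of mapped fragments) stand beside a lower and an upper limit for each group, and their program of origin is not given in the sources used here. Per the file headers, the deposited estimated counts are fragments assigned to each locus, and they need not be whole. Each table held 1 column per group, so the 2 libraries of a group were already combined by the authors. For this reason no SD, n or p-value across libraries is given. The authors' interval stands beside a value instead. The ratio of FPKM to count had a median of 1.00 between each treated group and the untreated group, so both tables carry the same scaling between groups. Total estimated counts were 84503307 in the untreated, 76501619 in the MM401, 88203834 in the Mll1_deleted and 90728747 in the 2i group.

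The tables held 61535 loci. Of these, 11475 carried no gene name and were left out of the comparisons. They held between 0.324% and 0.405% of the estimated counts of a group. A further 1793 loci joined several gene names, so that a gene and its overlapping or neighbouring genes could not be separated. Whether counting used strand is not given in the sources used here. Values with the status HIDATA (between 18 and 107 loci per group) were all listed at 0 and were treated as missing. All 31 mitochondrial loci were listed at 0 in every group, so the list of mitochondrially encoded transcripts gave no value. Of the gene names, 24 differed between the 2 tables, and names were taken from the FPKM table. Coordinates are from the files, mm10, counted from 1.

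The planned analysis for tables with 1 column per group was used, with no test. A locus was tested if its FPKM was at least 1 in either group. It counted as higher or lower if log2 of the ratio of FPKM + 1 was at least 1 in size, a 2-fold change. Such ratios understate the change of low loci. Separation of the authors' intervals was recorded beside each count. There were 6 comparisons. The 25 gene lists, the rules and the alternatives were fixed before the data were examined. For each list the median log2 ratio was set against the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. The central range holds 95% of the random lists. These percentiles describe the pooled values of these libraries and are not p-values.

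The genes named were chosen by a fixed rule. It took the target Kmt2a, the 6 largest changes in each direction with FPKM of at least 5 in either group and status OK (4 between treated groups), and the 2 largest changes of each list described. Most of the loci that the second part named were short RNA loci with few fragments. A further rule was therefore added after the data were seen. It required at least 100 estimated counts in either group and a 2-fold change in the same direction in the counts (pseudocount 10). Other list members are named as examples, chosen after their values were seen.

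The precision of a group value was checked on simulated data. Copies of the untreated group were drawn from a gamma distribution 20 times, with the authors' interval read in 1 reading as 2 SD of the group value and in the other as 2 SD of 1 library. Between simulated copies without any change, 1140.3 loci on average passed the 2-fold rule in the first reading and 750.2 in the second. Of these, 125.9 and 26 also had separate intervals. With the counts included, 734.1 and 401.2 passed. In the real comparison of Mll1_deleted with untreated cells 339 loci passed that rule, fewer than in either reading. The simulated spread may therefore be too wide, and these numbers are not a firm bound on chance. In the first reading, 95% of 100 genes planted with a 3-fold change among 13940 loci of at least 100 counts passed the rule, and 99% of 100 genes planted with a 6-fold change did. On the MM401 ratios of 16768 loci, 5% of 100 random lists of 20 genes fell outside the central range, and 100% of lists shifted by 1 log2 unit did. This checks the calculation only. Genes of a real list may move together, which random lists do not reproduce. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and gene model lengths came from GENCODE M21.

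The alternatives were pseudocounts of 0.1 and 5, no filter on low values, FPKM of at least 5, the median ratio of expressed genes set to 0, the count table, a 4-fold rule, separate intervals, and the omission of fibroblast genes with all loci of a status other than OK. The alternatives planned for tables with 1 value per library (edgeR, DESeq2, other normalizations, leaving out libraries and the gene set tests) could not be applied to these tables.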

Results

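RNA was sequenced from 8 libraries of mouse embryonic stem cells grown on feeder fibroblasts, in 4 groups of 2 libraries. The groups were untreated cells, cells given the MLL1 inhibitor MM401, cells in which the Mll1 gene (Kmt2a) was deleted, and cells given the 2 kinase inhibitors known as 2i. The deposited tables hold 1 value per group, so no value below carries a spread between replicates. Total estimated counts were 84503307 in the untreated, 76501619 in the MM401, 88203834 in the Mll1_deleted and 90728747 in the 2i group. Loci with a gene name and an FPKM of at least 1 numbered 15352, 15927, 15418 and 15023 in the same order. Values are FPKM, square brackets hold the authors' interval, and log2 ratios are of FPKM + 1 against untreated unless another group is named.

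Kmt2a, the target of both MLL1 treatments (chromosome 9, 44803333 to 44884397, mm10), had an FPKM of 15.5 [11.4 to 19.7] in untreated cells. It was 14.6 [10.3 to 18.8] in MM401, 11.8 [8.71 to 14.9] in Mll1_deleted and 8.72 [6.11 to 11.3] in 2i cells. None of the 3 log2 ratios (−0.09, −0.37 and −0.77) passed the 2-fold rule. In 2i alone the interval lay wholly below the untreated one. The value covers the whole gene, and the loss of a floxed exon need not lower it, so it does not measure how complete the deletion was.

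The first comparison asked what the MLL1 inhibitor changed. In MM401 cells Pou5f1 fell from 874 [689 to 1059] to 294 [222 to 366], and Lin28a fell from 109 to 15.1, while Nanog was 265 and 289. Lefty2 fell from 57.1 [44.7 to 69.5] to 2.08 [1.43 to 2.73], and Trh fell from 102 to 2.56. The p53 target Plk2 rose from 36.0 to 114, and the glycolytic enzyme gene Ldha fell from 264 to 76.0. Of 16768 loci tested, 1178 were higher and 1019 lower, of which 741 and 672 had separate intervals. The median ratio of expressed genes was −0.11. With that median set to 0, 1531 loci were higher and 810 lower.

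Several lists moved as groups in MM401 cells. Of 26 core and naive pluripotency genes 0 were higher, 11 lower and 15 neither, with a list median of −0.82, or −0.71 relative to all genes. Klf2 (−1.75), Nr0b1 (−2.57) and Lin28a (−2.77) were among the lower ones, whereas Esrrb (−0.19), Zfp42 (−0.16) and Fbxo15 (0.63) did not pass. Of 14 formative and primed epiblast genes 8 were lower and 0 higher, with a median of −1.20. The Zic2 locus, which also holds Zic5, had a ratio of −3.52, Lef1 of −2.68, the Dnmt3b locus of −2.51 and Fgf5 of −2.48. The Dnmt3b locus also holds Dnmt3c-ps. Of 8 genes of the DNA methylation machinery, 3 were lower (median −0.89), and they were Dnmt3a (−1.74), the Dnmt3b locus and Dnmt3l (−1.59). Of 15 glycolysis and hypoxia genes 8 were lower and 0 higher, with a median of −1.07 and with Ldha at −1.78 and Eno1 at −1.45. Each of these 4 medians lay below the central 95% of random lists of the same size.

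The p53 target list moved the other way, with 9 of 19 genes higher, 0 lower and a median of 0.98. Plk2 (1.63), Btg2 (1.54), Polk (1.39) and Mdm2 (1.22) passed the rule, and Cdkn1a (0.77) did not. Of 18 2-cell-like genes 6 were higher and 0 lower (median 0.78), led by the Tcstv3 locus (1.69) and the Tcstv1 locus (1.55), whose near-identical copies share reads, so single members are uncertain. Of 24 trophectoderm and trophoblast genes 6 were higher and 0 lower (median 0.50), among them Sct (2.72), Dlx3 (1.82), Wnt7b (1.73) and Id2 (1.54). Of 21 methylation-silenced germline genes 3 were higher (median 0.55), with Dpep3 at 2.34 and Mov10l1 at 1.41, the latter with overlapping intervals. These 4 medians lay above the central range of random lists.

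Primitive endoderm genes were lower in 8 of 24 cases in MM401 cells, with a median of −0.71, and Cubn had a ratio of −2.31 and Ttr of −1.94, both with overlapping intervals. Of 13 interferon response genes 6 were lower (median −0.87), with Ddx58 at −2.11 and Isg15 at −1.87. Fibroblast markers went the other way, with 3 of 29 higher, 1 lower and 25 above 0. They were listed to follow the feeder cells, but their source was not checked. Their median of 0.33 lay above the random range. Lox (1.51), Postn (1.29) and Thbs1 (1.21) were higher and Ccl2 (−1.08) was lower. Of 18 MEK-ERK feedback targets 4 were lower (median −0.42), with Spry4 at −1.96 and Dusp6 at −1.19. HOX cluster genes had 2 of 25 higher, Hoxc13 (1.41) and Hoxb13 (1.15), and a median of 0.40 inside the random range. The vitamin D and retinoid list had a median of −0.09, although Cyp26a1 (−3.85) fell from 36.4 to 1.60, and Stra6 (−1.08) was lower. Of 11 Wnt targets Nkd1 (1.08) was higher and Notum (−3.12) lower, with a median of 0.35 inside the random range. Of 15 cholesterol synthesis genes only Dhcr7 (1.35) passed, with overlapping intervals, and Insig1 was at 0.79.

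**Figure D1:**
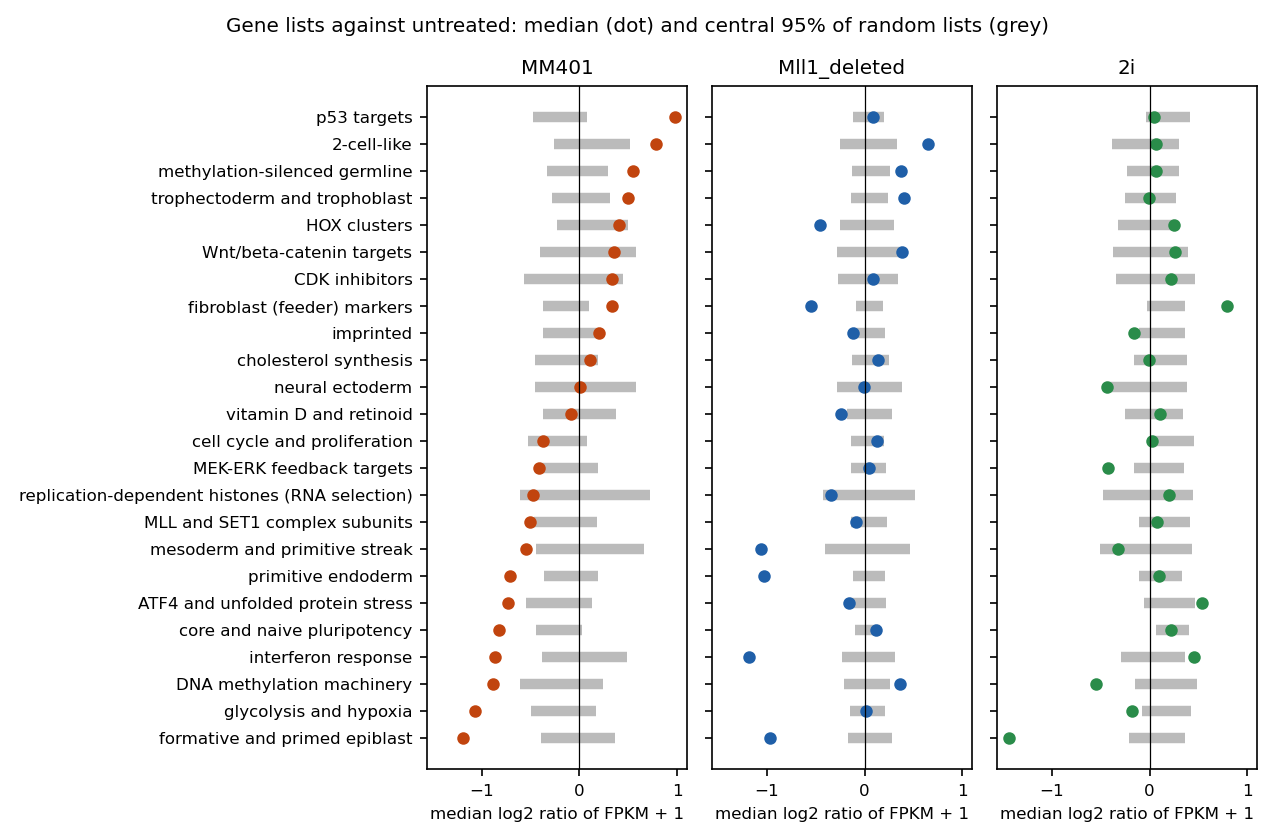
Median log2 ratio of FPKM + 1 of each gene list (dots) in MM401, Mll1_deleted and 2i cells against untreated cells, with the central 95% of 10000 random lists of the same size and expression (grey bars). The primed epiblast list lies below the bar in all 3 panels (−1.20, −0.96 and −1.44), and the p53 list lies above it in the MM401 panel alone (0.98).

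The largest ratios of all, by the rule fixed before the data were examined, came from loci of few fragments. Gm27786 was listed at 0 in untreated cells and at 169, 233 and 521 in MM401, Mll1_deleted and 2i cells, and these values rest on 14.8, 20.4 and 45.7 estimated counts. Gabrg3 was 89.0 in untreated cells from 3.61 counts and was listed at 0 in the other groups. Among loci with at least 100 counts whose counts also passed 2-fold, 628 were higher and 639 lower in MM401 cells, a total of 1267, above the 734.1 and 401.2 of simulated unchanged groups. The largest increases included those at Gm21542 (2.83), Arl4d (2.78), Sct, Ptx3 (2.57) and Ush1c (2.56). The largest decreases were at Trh (−4.85), Slc7a3 (−4.30), Lefty2 (−4.24), Cyp26a1, Zic2 and Spink1 (−3.41). Arl4d (chromosome 11, 101665541 to 101667832) rose from 8.92 [7.06 to 10.8] to 67.1 [54.7 to 79.6].

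The second comparison asked what deletion of Mll1 changed. Pluripotency genes did not pass the rule, and Pou5f1 was 1008 [793 to 1223] in deleted cells. Fgf5 fell from 8.66 [6.22 to 11.1] to 0.473 [0.299 to 0.648], and Otx2 fell from 33.2 to 10.2. Cyp26a1 fell from 36.4 [27.4 to 45.4] to 2.64 [0.788 to 4.49], and Gata6 fell from 10.8 to 3.45. Txnip rose from 135 to 506, and Dpep3 rose from 1.47 to 11.9. Of 16235 loci tested, 491 were higher and 595 lower, of which 244 and 331 had separate intervals. The 1086 loci past the rule did not exceed the 1140.3 that simulated unchanged groups gave in the wider reading of the intervals, but exceeded the 750.2 of the narrower one. The 575 with separate intervals exceeded the 125.9 and 26 of the 2 readings.

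In Mll1_deleted cells 0 of 26 pluripotency genes passed the rule, with a median of 0.11 inside the random range, and Dppa3 (−0.82) and Nr0b1 (−0.71) had the largest ratios. Of 14 primed epiblast genes 7 were lower and 0 higher (median −0.96), with Fgf5 at −2.71, Lef1 at −1.69, the Zic2 locus at −1.64 and Otx2 at −1.60. Of 24 primitive endoderm genes 13 were lower and 0 higher (median −1.03), with Srgn at −2.01, Ttr at −1.84, Foxa2 at −1.64 and Gata6 at −1.40, and the intervals of Ttr overlapped. Of 12 interferon response genes 8 were lower (median −1.18), and Isg15 had a ratio of −2.69 and an FPKM of 0.862 [0.400 to 1.32], below its untreated interval of 8.49 to 13.5. Fibroblast markers were also lower, with 4 of 29 past the rule and a median of −0.55, and Ccl2 (−1.76) and, with overlapping intervals, Tagln (−1.29) had the largest ratios.

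HOX cluster genes were inside the 2-fold bounds in all 18 cases in Mll1_deleted cells, but their median of −0.46 lay below the random range, with the Hoxb9 locus at −0.85 and Hoxb7 at −0.71. The HOX and fibroblast medians had the same sign in each treated group (−0.46 and −0.55 here, 0.40 and 0.33 in MM401, 0.25 and 0.79 in 2i). Of 15 2-cell-like genes 3 were higher (median 0.65), led by Usp17le (1.42) and the Tcstv1 locus (1.13), both uncertain for shared reads. Of 23 trophectoderm genes 4 were higher (median 0.41), with Hand1 at 2.07 and Krt7 at 1.30. Of 19 germline genes 3 were higher (median 0.38), with Dpep3 at 2.38 and, with overlapping intervals, Mov10l1 at 1.29. The DNA methylation machinery had a median of 0.37 above the random range, while the Dnmt3b locus (−1.32) was lower and Dnmt3l was at 0.69. The vitamin D and retinoid list had a median of −0.24 below the random range, with Cyp26a1 at −3.36 and Stra6 at −1.20. The p53 (0.08), glycolysis (0.01), MEK-ERK (0.04), cholesterol (0.14) and Wnt (0.38) medians lay inside it. In those lists Perp was at −0.61, Tnfrsf10b at 0.56, Ldha at −0.65, Spry4 at 0.74, Dhcr7 at 0.96 and Notum, the only one past the rule, at −1.68. The intervals of Tnfrsf10b, Ldha and Dhcr7 overlapped.

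With the counts included, 133 loci were higher and 206 lower in Mll1_deleted cells. The total of 339 was below the 734.1 and 401.2 that simulated unchanged groups gave under this rule. Of these, 103 and 166 had separate intervals, where the simulations gave 91.6 and 17.1 in total. The largest increases were at AC027700.2 (3.03), Tgm2 (2.46), Dpep3, Ly6k (2.04), Pde8a (1.92) and Txnip (1.90). The largest decreases were at Gm5566 (−4.27), Gm10800 (−3.49), Cyp26a1, Gm10801 (−3.07), Pga5 (−3.01) and Spink1 (−2.94). Gm10801 (98662237 to 98664083) and Gm10800 (98666547 to 98667301) lie close together on chromosome 2. Whether they share reads was not checked, so these loci are uncertain. The intervals of Pde8a and Gm5566 overlapped. Tgm2 (chromosome 2, 158028477 to 158146436) rose from 2.78 [1.04 to 4.51] to 19.7 [8.49 to 31.0], and Pga5 (chromosome 19, 10668957 to 10678071) fell from 58.1 [47.3 to 68.9] to 6.36 [4.97 to 7.75].

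The third comparison asked what MEK and GSK3 inhibition in serum replacement changed. Klf2 rose to 255 [214 to 295], above its untreated interval of 77.6 to 112, and Gbx2 fell from 17.1 to 5.18, while Pou5f1 was 1196 [945 to 1448]. Fgf5 fell to 0.498 [0.181 to 0.814] and the Dnmt3b locus fell from 89.5 to 24.8. The Wnt targets Axin2 and Cdx1 rose from 4.38 to 10.6 and from 1.09 to 7.12. The fibroblast collagen gene Col1a1 rose from 79.5 [66.9 to 92.1] to 402 [335 to 469]. Of 16039 loci tested, 469 were higher and 667 lower, of which 274 and 346 had separate intervals. The median ratio of expressed genes was 0.14, and with it set to 0, 344 loci were higher and 912 lower. The total of 1136 was below the simulated 1140.3 of the wider reading and above the 750.2 of the narrower one, and the 620 with separate intervals were above 125.9 and 26.

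In 2i cells 1 of 26 pluripotency genes was higher, Klf2 (1.41), and 1 was lower, Gbx2 (−1.55), with a median of 0.22 inside the random range. Of 14 primed epiblast genes 8 were lower and 0 higher (median −1.44), with Fgf5 at −2.69, Pou3f1 at −2.34, Lef1 at −1.96 and Otx2 at −1.93. Of 8 genes of the DNA methylation machinery 2 were lower, the Dnmt3b locus (−1.81) and Dnmt3a (−1.74), with a median of −0.55. None of 18 MEK-ERK feedback targets passed the rule, but their median of −0.43 lay below the random range, with Dusp4 at −0.97 and Spry4 at −0.84. Of 9 Wnt targets 3 were higher and 0 lower, Cdx1 (1.96), Dkk1 (1.39) and Axin2 (1.10), with a median of 0.26 inside the random range. Of 29 fibroblast markers 11 were higher and 1 lower (median 0.79), with Col1a1 at 2.32, the Col3a1 locus at 1.78 (overlapping intervals) and Ccl2 at −1.11. Of 13 interferon genes 3 were higher (median 0.46), with Irf7 at 1.38 (overlapping intervals) and Usp18 at 1.07.

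Of 24 primitive endoderm genes 3 were higher and 1 lower in 2i cells (median 0.10), with Cited1 at 1.79 and Sox17 at 1.24. The glycolysis median of −0.18 lay below the random range, and Pdk1 (−1.27) was lower. Medians inside the random range were those of the p53 (0.04), 2-cell-like (0.07), trophectoderm (−0.01), germline (0.06), HOX (0.25) and vitamin D and retinoid (0.11) lists, though the HOX median lay above it in the counts (0.42) and under 4 other alternatives. In those lists Pmaip1 (−1.01) was lower and Rhox6 (1.14, overlapping intervals) and the Hoxc5 locus (1.01) higher. The Gm12794 locus, which also holds Gm12800, was at −0.87 and Rpl10l at 0.98. The joint locus of Cyp27b1 and Mettl1 was at 0.62. Hmgcs1 was at −0.80 in the cholesterol list, whose median was −0.00. With the counts included, 180 loci were higher and 223 lower, and the total of 403 was below the simulated 734.1 and close to 401.2. Of these, 146 and 172 had separate intervals, against the simulated 91.6 and 17.1. The largest increases were at Clec3b (3.03), S100g (2.53), Trpm1 (2.49), Prelp (2.40), Col1a1 and 1500015O10Rik (2.14). Col1a1 belongs to the fibroblast list, whose median of 0.79 lay above the random range. Whether the share of feeder cells differed in 2i cultures was not tested. The largest decreases were at Spink1 (−4.43), Gm5566 (−3.67), Gm26363 (−3.50), Car4 (−2.98), Fgf5 and Gm27903 (−2.63). The intervals of Gm5566, Gm26363 and Gm27903 overlapped, and the count ratios of the last 2 were smaller (−1.40 and −1.41).

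**Figure D2:**
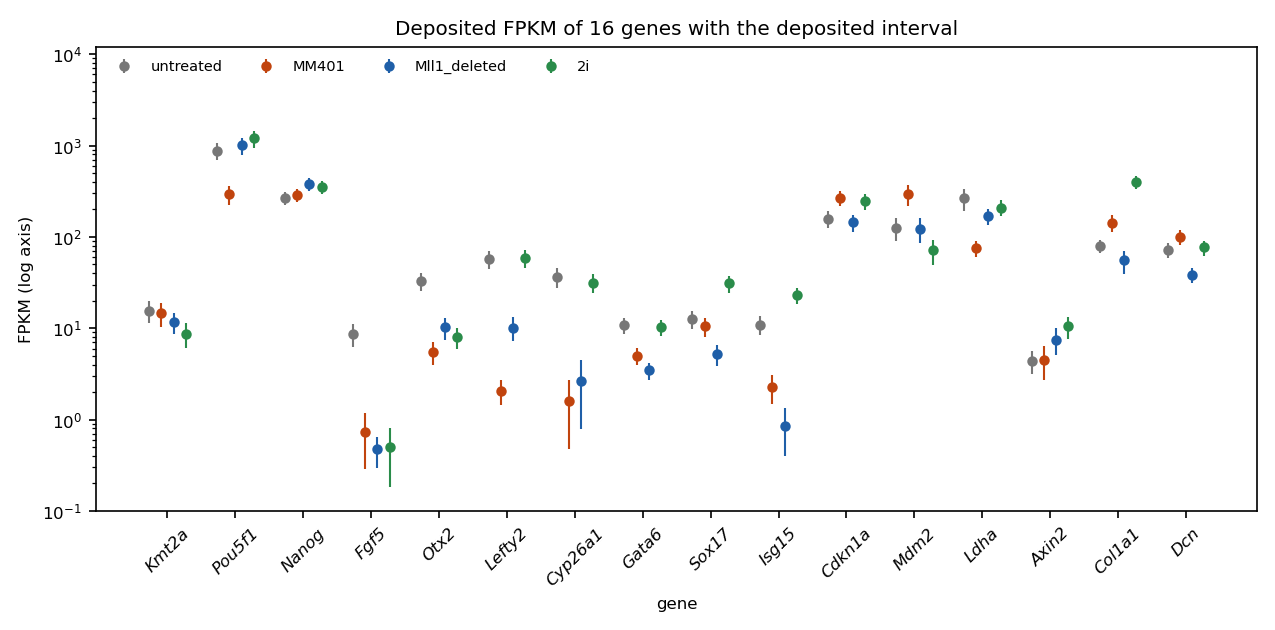
Deposited FPKM (log axis) of 16 genes in the 4 groups, with points for the group values and bars for the authors' interval. Fgf5 is lower in all 3 treated groups (0.734, 0.473 and 0.498 against 8.66), Pou5f1 in MM401 alone (294 against 874), and Col1a1 is highest in 2i (402).

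Between MM401 and Mll1_deleted cells, of 16668 loci tested, 919 were higher and 839 lower in MM401, of which 560 and 518 had separate intervals. The median ratio was −0.16, and with it set to 0 the numbers were 1299 and 553. Of 26 pluripotency genes 14 were lower in MM401 and 1 higher (median −1.05), and Pou5f1 was at −1.78. Of 8 genes of the DNA methylation machinery 5 were lower (median −1.18). Of 29 fibroblast markers 14 were higher and 0 lower (median 0.94), and of 19 p53 targets 7 were higher (median 0.90). Of 15 glycolysis genes 8 were lower, with a median below the random range, and of 23 HOX genes 4 were higher (median 0.69). With the counts included, the largest increases were at the Gria4 locus (3.69), Gm5566 (3.47), Gkn2 (3.02) and the Slpi locus (2.98), and the intervals of the first 2 overlapped. The count ratio of the Gria4 locus was 1.24. The largest decreases were at Slc7a3 (−3.28), Spry4 (−2.70), Foxd3 (−2.56) and Enpp3 (−2.53).

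MM401 and 2i cells differed at more loci than any other pair, with 1739 higher and 1857 lower in MM401 of 16775 tested, and 1081 and 1384 with separate intervals. The median ratio was −0.24, and with it set to 0 the numbers were 2677 and 1027. Trh (−5.18), S100g (−4.75), Slc7a3 (−4.61) and Lefty2 (−4.28) were lower in MM401, and Gm26363 (5.42), the Gria4 locus (3.76), Sct (3.38) and the Mir378b locus (3.35) were higher, with overlapping intervals at these except Sct. The count ratios of Gm26363, the Gria4 locus and the Mir378b locus were 2.01, 1.42 and 1.56. Interferon genes were lower in 10 of 13 cases (median −1.64), and ATF4 and unfolded protein stress genes in 7 of 13 (median −1.23). Mll1_deleted and 2i cells had 967 loci higher and 841 lower of 16224 tested, and 555 with separate intervals in each direction. S100g (−4.99), Saa3 (−4.17), Isg15 (−3.68) and Aqp8 (−3.43) were lower in Mll1_deleted, and the Mir378b locus (4.19), Gm26363 (3.90), the Cacng8 locus (3.72) and Gm26490 (2.81) were higher, the last 3 with overlapping intervals. The count ratios of the first 3 were 1.16, 1.40 and 2.28. Fibroblast markers were lower in 18 of 29 cases (median −1.25) and primitive endoderm genes in 13 of 23 (median −1.34).

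The last comparison asked how far the treatments changed the same genes. MM401 and deletion shared 211 higher and 305 lower loci of 15897 tested in both, where independent changes would give 18.2 and 38.1, and 30 went opposite ways. MM401 and 2i shared 112 higher and 286 lower of 15622, and 71 were opposite. Deletion and 2i shared 71 higher and 312 lower of 15573, and 65 were opposite. The untreated group enters both sides of each pair and raises these overlaps. Across genes, which are not independent replicates, Spearman's rank correlation was 0.51, 0.04 and 0.19 in the same order. Among loci of at least 100 counts Pearson's r was 0.53, 0.05 and 0.18, where simulated unchanged groups gave 0.59. Over all tested loci Pearson's r was 0.58, 0.26 and 0.41, and simulated unchanged groups with a shared control gave 0.60. Changes particular to 1 treatment lower r and are absent from the simulated groups. An r below the simulated one therefore does not tell whether more than the control is shared. The simulated groups also gave 176 shared higher and 301 shared lower loci in the wider reading of the intervals and 118 and 198 in the narrower one. With the counts included, 40 loci were lower in all 3 treated groups, and 1, Arrdc4, was higher, where simulated unchanged groups gave 113 and 58.0 in the wider reading and 64.7 and 31.4 in the narrower one. Under this rule MM401 and deletion shared 61 higher and 89 lower loci, MM401 and 2i 18 and 72, and deletion and 2i 3 and 56, none above the simulated 62.1 and 94.6 of the narrower reading. The covariance of log2 ratios was 0.139 for MM401 with deletion, 0.015 for MM401 with 2i and 0.037 for deletion with 2i. Simulated unchanged groups gave 0.172 in the wider reading and 0.095 in the narrower one. The first pair lay between these simulated values and the others below both. The simulated spread may thus be too wide, so the simulations do not decide whether these changes exceed what a shared control gives. The same control enters all 3 pairs, so it alone does not give the difference between their covariances. MM401 and deletion cultures also shared serum medium. Examples of the 40, chosen after their values were seen, are Fgf5, Otx2, Lef1, Lefty1, Cer1, Spink1 and Car4.

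**Figure D3:**
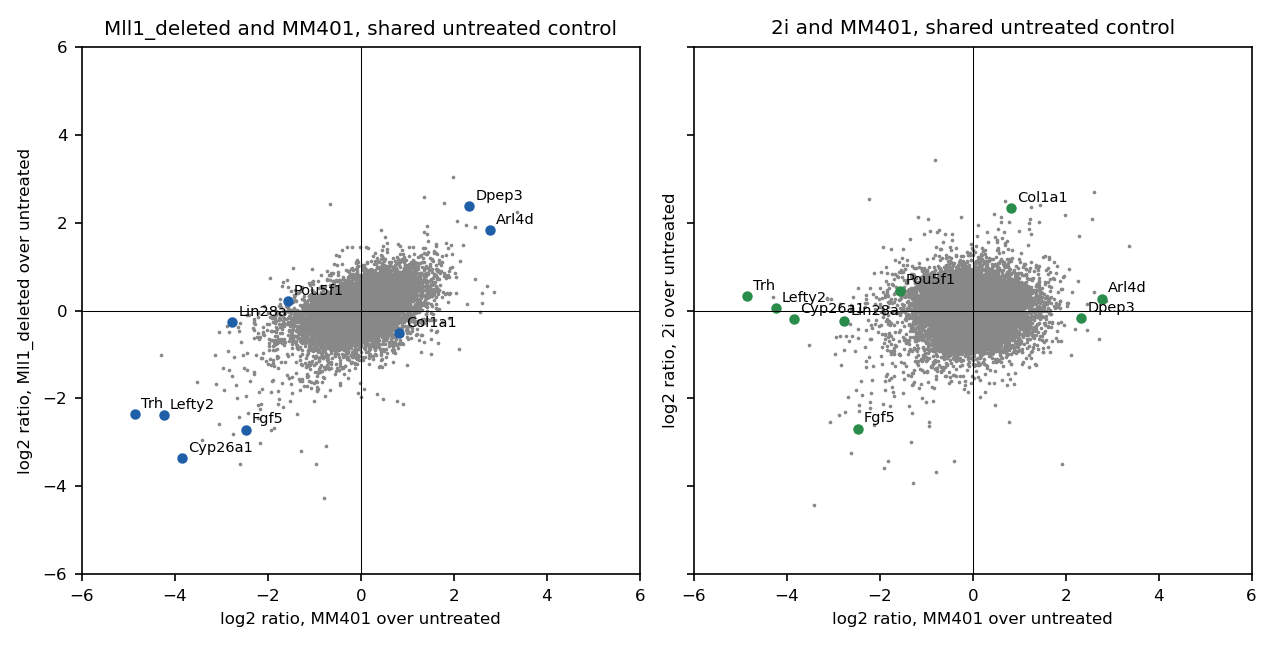
Log2 ratio of FPKM + 1 in Mll1_deleted (left) or 2i cells (right) against that in MM401 cells, all over the same untreated group, for 14223 loci with at least 100 estimated counts in any group. Lefty2 and Trh are low in MM401 and Mll1_deleted cells (Lefty2 −4.24 and −2.38, Trh −4.85 and −2.35) and near 0 in 2i cells (0.05 and 0.33).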

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

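The tests on feeder cells and on the share of stem cells in this part were chosen after the results were seen.

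The comparisons did not use the loci without a gene name, which held between 0.324% and 0.405% of the counts of a group. The numbers below have no filter on counts and were not set against simulated groups, so they need not be more than noise. Past the 2-fold rule, 1542 of them were higher in MM401 than in untreated cells, 635 in Mll1_deleted and 576 in 2i, while 792, 827 and 925 were lower. In untreated cells the highest FPKM among them, 7276 on chromosome 5 from 28093915 to 28093938, rested on 4.62 estimated counts. The same locus was at 7630 in 2i cells, from 4.85 counts. No explanation was tested for these loci.

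After Mll1 deletion 13 of 24 primitive endoderm genes, 8 of 12 interferon genes and 4 of 29 fibroblast markers were lower (medians −1.03, −1.18 and −0.55). If fewer feeder cells were the whole source, and feeder cells alone expressed the fibroblast markers, the lists would not lie below the fibroblast median. The primitive endoderm median minus the fibroblast median was −0.48 (bootstrap interval −0.73 to −0.08). The interferon difference was −0.63, with an interval of −1.01 to 0.10. These bootstrap intervals resample genes and hold no spread between libraries, and the source of the fibroblast markers was not checked. If feeder cells alone express these markers, the primitive endoderm difference argues against fewer feeder cells as the whole source of that list. A smaller share of feeder cells stays open as a part of that source. For the interferon list it stays open as the whole or a part. The authors' intervals lay wholly below the untreated lower limit times the fibroblast median ratio for 9 of 24 primitive endoderm genes, 7 of 12 interferon genes and 1 of 29 fibroblast markers (Ccl2). A change within the feeder cells, an effect of 4-hydroxytamoxifen, or lower expression after loss of MLL1 may each lie behind either list, and these stay open and untested.

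In MM401 cells 11 of 26 pluripotency and 8 of 15 glycolysis genes were lower and 9 of 19 p53 targets higher, and the other members did not pass the rule. A smaller share of stem cells would lower all pluripotency genes by about the list's median of −0.82. Some members lie above their own list's median by construction, so only intervals wholly above the untreated upper limit times that ratio were counted. There were 7 of 26, Nanog, Esrrb, Tbx3, Zfp42, Dppa3, Dppa5a and Fbxo15, which argues against a smaller share of stem cells as the whole source. Fibroblast markers had a median of 0.33, with 25 of 29 above 0, which goes with a smaller share of stem cells, so it stays open as a part of the source. An effect of MLL1 inhibition and another effect of the compound may both be involved, and no vehicle or inactive compound was among the groups to separate them.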

How the results depend on the processing

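The rules of at least 100 counts, of FPKM and counts together, of HIDATA taken as 0, and of list members left out were added after the data were seen. Counts below are of loci past the rule, in the order MM401, Mll1_deleted and 2i against untreated, MM401 against Mll1_deleted, and Mll1_deleted against 2i, unless stated. MM401 against 2i is given apart.

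A pseudocount of 0.1 gave 3436, 1772, 1821, 2764 and 2884, and a pseudocount of 5 gave 803, 352, 386, 639 and 622. An FPKM of at least 5 gave 1401, 600, 637, 1153 and 1159. A 4-fold rule gave 433, 320, 327, 382 and 401. Separate intervals gave 1413, 575, 620, 1078 and 1110. At least 100 counts gave 1406, 413, 469, 1003 and 1084, and FPKM with counts gave 1267, 339, 403, 895 and 982. MM401 against 2i fell outside 1.5 times its number only at a pseudocount of 5 (1527) and at 4-fold (593). These rules differ from the reported one in strictness, which by construction alters the count.

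For shared changes, a pseudocount of 0.1 gave 924 for MM401 with deletion and 600 for MM401 with 2i. A pseudocount of 5 gave 159, 129 and 117 for these pairs and for deletion with 2i. An FPKM of at least 5 gave 282, 197 and 177, 4-fold gave 138, 118 and 125, and FPKM with counts gave 150, 90 and 59.

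All 6 comparisons stayed within 1.5 times their numbers with the median of genes set to 0, with the count table, with fibroblast genes and other statuses left out, and with HIDATA taken as 0. The count table shared 1336 of 2197, 377 of 1086 and 448 of 1136 loci with the FPKM table against untreated. Leaving out the filter on low values cannot alter a count, since 2-fold with a pseudocount of 1 needs an FPKM of 1. Kmt2a ratios from counts were 0.04, −0.08 and −0.88.

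Of 144 list medians over the 6 comparisons, 67 lay outside the random range. Setting the median of genes to 0 moves a list and its random lists alike and so cannot alter this. Under the other 5 alternatives these gave 335 values, of which 16 came to lie inside the range and 0 had another sign. Of 385 values for the other lists, 36 came to lie outside. Against untreated, these were as follows. With counts, the pluripotency median in Mll1_deleted, the HOX medians in MM401 and 2i, the Wnt medians in MM401 and Mll1_deleted and the imprinted median in MM401 came to lie outside, and the neural median in 2i and the MLL complex median in MM401 inside. The HOX median in 2i lay outside under each of the 5. At a pseudocount of 0.1 the Wnt median in Mll1_deleted and the imprinted median in MM401 lay outside and the neural median in 2i inside. At a pseudocount of 5 the MEK-ERK and MLL complex medians in MM401 and the ATF4 median in Mll1_deleted lay inside. With members of low FPKM included, the HOX, imprinted and histone medians in MM401 lay outside, and the trophectoderm and vitamin D medians in Mll1_deleted, the neural and interferon medians in 2i and the mesoderm median in MM401 inside. With members left out, the imprinted median in Mll1_deleted lay inside. The cause was not tested.

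No paired analysis was possible because the columns carry no replicate numbers. For the same reason libraries could not be left out, controls could not be split, and edgeR, DESeq2, camera, fry, the replicate block, the other normalization, the filter on counts and the fit of only the groups compared were not run. Depth limits loci of few fragments. Under 100 counts lay 470 of the 1178 higher loci in MM401, 314 of 491 in Mll1_deleted and 254 of 469 in 2i.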

Other observations

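The tests of NODAL pathway genes and of short gene models had bounds written before their results were computed, but the NODAL test was divided by group after its result was seen, and the reading of low counts as 2 libraries was chosen after the values were seen.

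ATF4 and unfolded protein stress genes had a median of −0.73 in MM401, where Chac1 (−1.73) was lower and Ddit3 (1.89) higher, of −0.16 in Mll1_deleted, where Atf3 was at −0.56, and of 0.54 in 2i, where Trib3 (1.24) and Asns (1.19) were higher. All 3 medians lay outside the random range, although that of Mll1_deleted did so narrowly and lay inside at a pseudocount of 5. Of 15 cell cycle genes 4 were lower in MM401, among them Ccnd1 (−1.98) and Ccne1 (−1.66), with a median of −0.38 inside it, and the medians were 0.13 and 0.02 in the other groups. The CDK inhibitor medians were 0.34, 0.08 and 0.22, and Cdkn1c was higher in MM401 (1.37) and Mll1_deleted (1.11). MLL and SET1 complex subunits had medians of −0.51, −0.09 and 0.08, and Setd1b (−1.36) was lower in MM401.

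Among lineage genes, mesoderm and primitive streak medians were −0.55, −1.07 and −0.33, and Cer1 (−2.21, −2.14 and −2.21) and Lhx1 (−1.93, −1.25 and −2.12) were lower in every treated group. Neural ectoderm medians were 0.00, −0.01 and −0.44, with Olig2 lower in MM401 (−1.68). In 2i Sox1 (−1.49) and the Neurod1 locus (−1.37), which also holds Cerkl, were lower. Imprinted genes had medians of 0.20, −0.12 and −0.16, with Grb10 (−1.57) lower in MM401, Cdkn1c higher in Mll1_deleted and Peg3 (−1.74) lower in 2i. Replication-dependent histones had medians of −0.48, −0.34 and 0.20 inside the random range, with 0 past the rule. Mitochondrially encoded transcripts were listed at 0.

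Lefty1 (−3.06 and −2.59), Lefty2 and Cer1, genes that NODAL signalling induces, were lower in MM401 and Mll1_deleted cells. In 2i cells Lefty1 (−2.53) and Cer1 (−2.21) were lower too, and Lefty2 was at 0.05. If lower expression of this pathway lay behind that, at least 3 of Nodal, Smad7, Skil, Tdgf1, Gdf3 and Foxh1 were to be lower. In MM401 3 of 6 were, Tdgf1 (−1.56), Gdf3 (−1.33) and Foxh1 (−1.92), which may also be part of the shift of the pluripotency list, where 11 of 26 were lower. In Mll1_deleted 0 of 6 were, which argues against lower expression of these pathway genes there.

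FPKM and counts of a locus did not always move together. Of the loci past the rule with at least 100 counts and a known model length, the counts did not pass at 135 in MM401, 72 in Mll1_deleted and 64 in 2i. The locus of Xist, which also holds 2 short gene models, went from 33.3 to 5.33 in FPKM in MM401 while its estimated counts went from 2144 to 3766. Short gene models may be the source, since 41.0% of such loci held a model under 200 bases, against 1.74% of loci where both passed. The bound was set before the share was computed, although single examples had been seen.

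The tables also hold traces of the single libraries. Low estimated counts lay at sums of whole multiples of 2 steps per group, within 0.0001 counts for 86.1% of untreated values under 5 counts, where chance gives 0.285%. Read as the 2 libraries of a group, the steps differ by factors of 1.51, 1.51, 1.09 and 1.23 in untreated, MM401, Mll1_deleted and 2i cells.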
